A study of Homo sapiens with 15 samples.

How the data were processed

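Total RNA of human U87 glioblastoma cells had been measured on 15 Affymetrix arrays (HG_U95Av2, 12625 probe sets, 67 of them controls). Per the labels, 3 arrays each came from the parental line, from the neomycin-resistant negative control clones 3.1 and 3.3, and from clone 8.1, which expresses the dominant-negative PDGF-A, without and with PDGF. The labels give no form, dose or time for PDGF and do not say whether the chips of a group were separate cultures or separate hybridizations, so n counts arrays.

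The deposited table holds 1 intensity value per probe set and array, on a linear scale, between 0.2 and 107654. The deposited intensities were used as given. The summarisation software and the scaling target are not stated, but the mean of each array with 2% taken off each end lay between 1500.62 and 1500.73, so the authors had scaled each array to the same trimmed mean. The other deposited text, per the file headers, is the run information of 14 of the arrays (chip type, chip lot, fluidics and scan), and it holds no probe values. Clone 3.1 replicate 3 had no such information. From these fields came 5 scan days, 4 chip lots and a remark on 2 arrays (clone 8.1 no PDGF replicate 1 and parent replicate 3) that the scan was delayed. The run information of clone 3.1 replicate 2 and of parent replicate 3 words the sample differently from that of the other arrays of their groups, and the titles were followed. Days and lots are given here only as numbers. Replicate numbers follow the chip numbers in the titles, except that 1 title of clone 8.1 without PDGF has no number and was taken as replicate 2.

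Values were raised by an offset equal to the 10th percentile of the positive values of the table (29.9) and log2 transformed. Array medians lay between 434 and 529 (1.22-fold apart, under the limit of 1.5-fold set for normalizing again), so the deposited scaling was kept. Control probe sets and the 40% of probe sets with the lowest mean over all arrays were left out, which left 7535 probe sets. Of these, 6706 carried 1 gene symbol (5482 genes), 363 several and 466 none. No 2 arrays were identical, the lowest correlation between any 2 arrays was 0.886, and within groups it was 0.928 to 0.984.

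Comparisons were made in R 4.3.3 with limma 3.58.1. A linear model of 5 group means was fitted to all 15 arrays (10 residual degrees of freedom), with empirical Bayes moderation without a trend, and p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison. A probe set was called at an adjusted p under 0.05. The comparisons were clone 8.1 without PDGF against the mean of the neo clones, PDGF added to clone 8.1, the probe sets called in both with opposite signs, clone 8.1 with PDGF against the neo clones, clone 3.1 against clone 3.3, the neo clones against the parent, and clone 8.1 without PDGF against the parent. Errors are standard errors of the log2 change from the model. Group intensities are means of the deposited values with their standard deviation.

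Named genes were chosen by a rule fixed in advance, from probe sets with 1 gene symbol and with the brightest probe set of each gene. For clone 8.1 without PDGF against the neo clones, and for PDGF added, these are the 10 genes that rose most and the 10 that fell most among called probe sets whose arrays did not overlap. The opposed set adds the 10 genes with the largest smaller change, and each other comparison the 5 at either end. PDGFA, PDGFB, PDGFRA, PDGFRB, SREBF1 and SREBF2 were named wherever measured, as were up to 4 members of each list with the largest moderated t.

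A total of 15 gene lists were fixed in advance: sterol synthesis and uptake, fatty acid synthesis, PDGF family and SREBP genes, immediate early genes, ERK feedback and output genes, DNA replication, mitosis, extracellular matrix, contractile cytoskeleton, glycolysis and hypoxia, unfolded protein response, p53 targets, interferon response, inflammatory cytokines and NF-kB targets, and heat shock. A further 6 lists hold markers of astroglial, oligodendroglial, neuronal, immune, epithelial and fibroblast or mural cells. Lists were tested by limma's camera with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. A list with fewer than 3 measured members was not tested. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members of 1 list.

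The overlap of the 2 main comparisons was set against the overlap of independent lists and against 100 simulated data sets in which no group differed, and later against splits of the 3 arrays that the comparisons share, with the spread of the 5-group model. The overlap of clone 8.1 without and with PDGF, both against the neo clones, was treated likewise, with the 6 neo arrays split 3 and 3. The pipeline was also tested on simulated data with 200 of 7535 probe sets changed in clone 8.1 without PDGF. It called 84% of those changed 2-fold and 24% of those changed 1.5-fold against the neo clones, and 64% and 12% with PDGF added. Of the probe sets called there, 160 and 141, 6 and 4 had not been changed. It also called the 1 list that had been shifted out of 15, with both correlations. The simulated errors were independent between genes, so this does not test the estimated correlation for lists whose members vary together.

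As alternatives, the offset was set to 1 or to the 25th percentile, the intensity filter was left out or raised to 60%, arrays were quantile normalized or scaled to equal medians, and moderation was used with a trend. Others limited the model to the groups compared, left out each array in turn, took chip number or chip lot as a block, and asked for an adjusted p under 0.01 or a 2-fold change. The control was also taken as clone 3.1 alone, clone 3.3 alone, all 3 control lines, or 1 mean per line, and lists were tested on the mean of all probe sets of a gene. Scan day as a block could be fitted only where scan days hold both groups, and not for PDGF added to clone 8.1. After the data were seen, scan-day blocks with 1 neo clone as the control, scan day as a random block, and fits without the delayed-scan arrays were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.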

Results

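Gene expression was measured in U87 cells, an established human glioblastoma line, on 15 Affymetrix arrays of 12625 probe sets. The arrays fall into 5 groups of 3: the parental line, the neomycin-resistant control clones 3.1 and 3.3, and clone 8.1 without and with added PDGF. Clone 8.1 expresses a dominant-negative form of platelet-derived growth factor A (PDGF-A). The control clones are called the neo clones here (6 arrays). Every log2 change is given ± SE, with n = 3 arrays for clone 8.1 in either state, 3 for the parent and 6 for the neo clones. The labels name neither the form of PDGF, nor its dose, nor the time of exposure. Clone 8.1 was the only line with the construct, so the design does not separate the construct from the clone. The labels also do not say whether the chips of a group came from separate cultures, so the p-values measure a spread between arrays that may be technical. Median intensity per array lay between 434 and 529, and the arrays of a group correlated with r between 0.928 and 0.984 over the log2 values. The keywords in the labels name the sterol regulatory element binding protein (SREBP), so the lists of sterol and fatty acid genes are not independent evidence of the direction. The gene lists, the rule for named genes and the limma and camera tests of the comparisons were fixed before the data were examined. The values within scan days and chip lots, and the scan-day block with clone 3.1 alone as the control, were added later.

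The comparison of clone 8.1 without added PDGF with the neo clones asks which transcripts depend on PDGF signalling, the question in the title of the series. The genes of cholesterol and fatty acid synthesis fell together in clone 8.1. HMGCS1, an early enzyme of the mevalonate pathway, had an intensity of 7893 ± 208 (SD, n = 6) in the neo clones and of 279 ± 80.2 (SD, n = 3) in clone 8.1, a log2 change of -4.71 ± 0.17 (adjusted p = 7.25e-10). MVD, the decarboxylase of the same pathway, changed by -5.05 ± 0.21 (adjusted p = 1.23e-09), and the sterol enzymes IDI1 and MSMO1 by -2.46 ± 0.12 and -3.16 ± 0.16. FASN, the fatty acid synthase, changed by -2.72 ± 0.11 (adjusted p = 1.23e-09). The desaturases FADS2 and SCD changed by -3.74 ± 0.34 and -3.11 ± 0.31, and LPIN1, a phosphatidate phosphatase, by -2.32 ± 0.18. Of the 24 genes fixed for sterol synthesis and uptake, 16 were measured and 14 fell, 15 when adjusted over the list alone. None rose, and the median was -1.97 (limma camera adjusted p = 8.40e-27, and adjusted p = 0.00564 with an estimated correlation). Of 19 fatty acid genes, 11 were measured and 9 fell by either count, with a median of -1.13 (adjusted p = 1.67e-12, and adjusted p = 0.00564 with an estimated correlation). Scan days 2 and 3 each held 1 array of clone 8.1 and 1 of clone 3.1. Within them the sterol median was -1.83 and -1.87, and the fatty acid median -1.40 and -0.96. With chip lot as a block, the median of both lists pooled was -1.80, as without it.

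**Figure D1:**
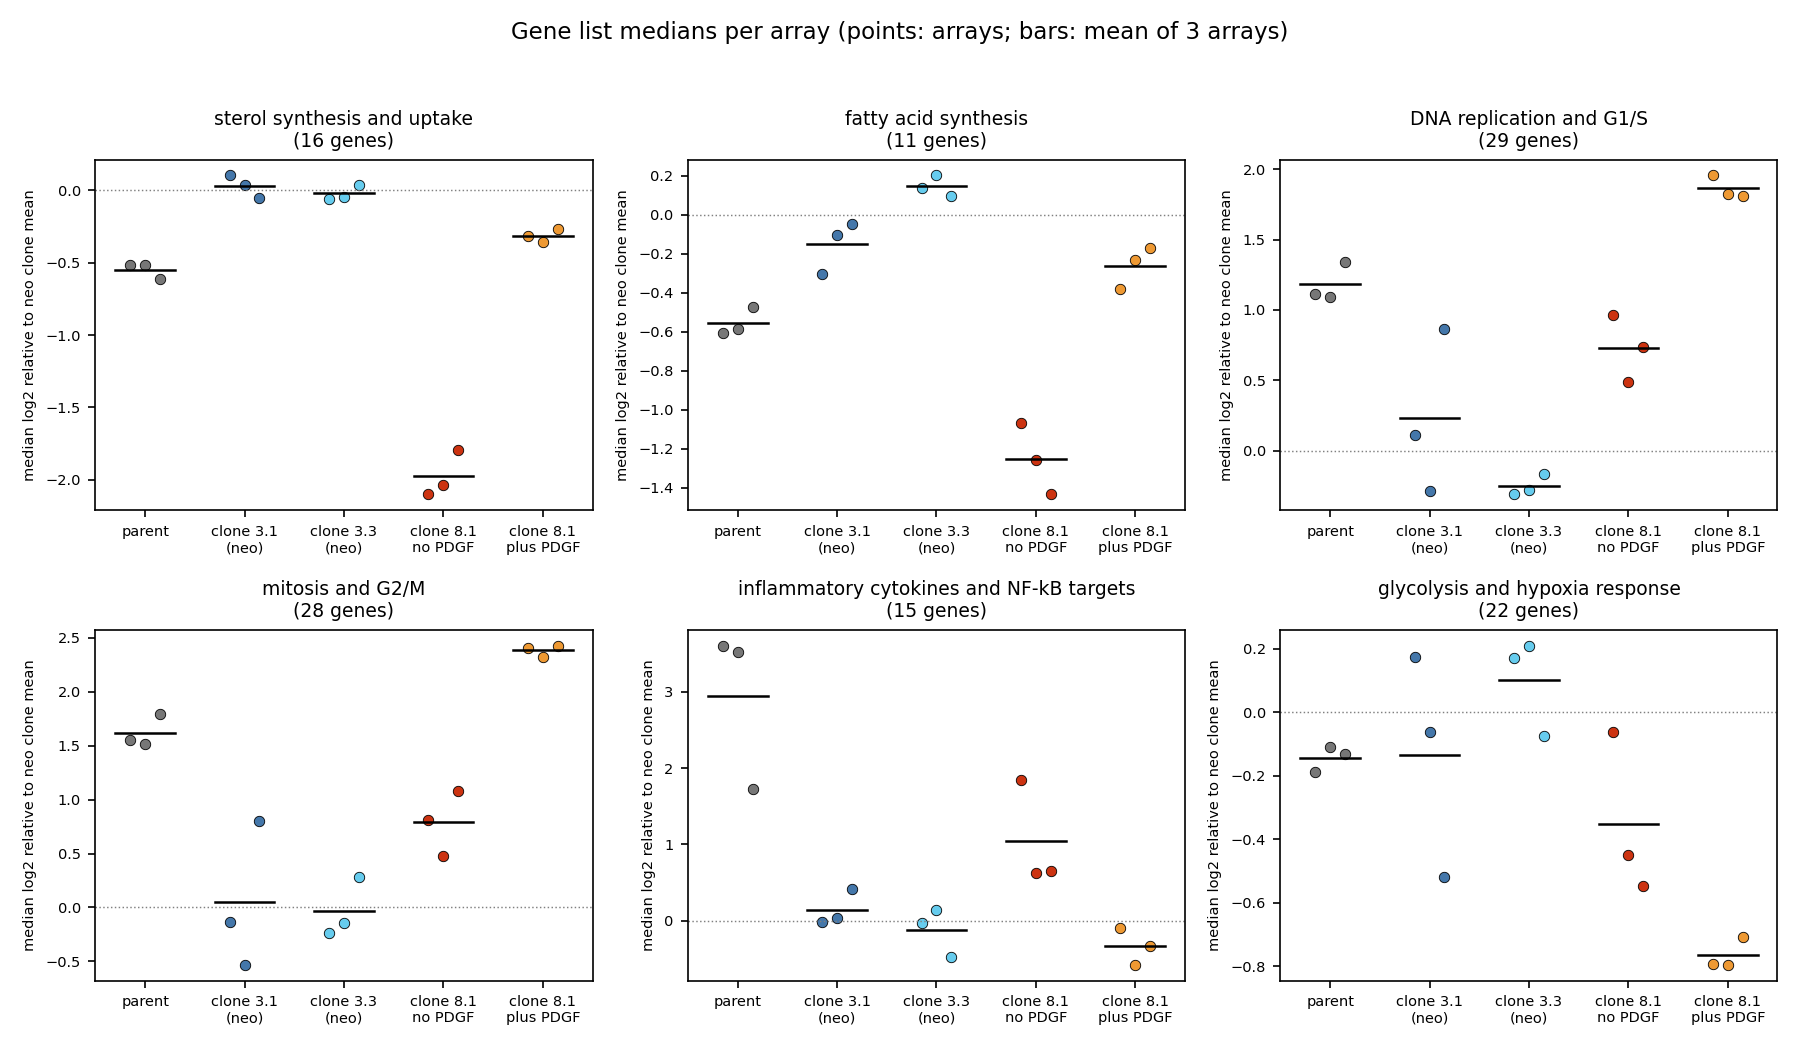
Median log2 intensity of 6 gene lists on each of the 15 arrays, relative to the mean of the neo clones; each point is 1 array, grouped by cell line and treatment. On the sterol list the 3 arrays of clone 8.1 without PDGF lay at -2.10, -2.04 and -1.79, and the 3 arrays with PDGF at -0.32, -0.35 and -0.27.

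CH25H, which makes an oxysterol that restrains SREBP processing, rose from 613 ± 75.2 (SD, n = 6) to 6584 ± 295 (SD, n = 3), a log2 change of 3.37 ± 0.23 (adjusted p = 4.32e-07). With PDGF added CH25H changed by -1.34 ± 0.27 (limma adjusted p = 0.00515). It still lay 2.03 ± 0.23 above the neo clones with PDGF (adjusted p = 2.49e-05), and its link to the lipid genes was not tested. Without PDGF, the chemokine CCL2 rose by 3.09 ± 0.39 (adjusted p = 1.31e-04), the proteoglycan LUM (lumican) by 2.77 ± 0.48 and the collagen COL15A1 by 2.85 ± 0.29. LRRC17, TSPAN7, IGFBP4, PADI2, CHI3L1 and IGFBP5 completed the 10 largest increases, between 2.37 ± 0.44 for IGFBP5, an insulin-like growth factor binding protein, and 2.88 ± 0.25 for LRRC17. Against the parent, CCL2, COL15A1, IGFBP4 and IGFBP5 were not called (1.35, 0.27, 1.06 and 1.57, limma adjusted p from 0.0565 to 0.692), and the others were. COL15A1 was at 1174.7 in the parent and at 172.5 in the neo clones. The largest decrease was that of CD24, a surface glycoprotein, at -5.39 ± 0.46 (adjusted p = 3.49e-06). CD24 was high only in the neo clones, however, at 3301 ± 1406 (SD, n = 6) against 85.9 ± 27.5 (SD, n = 3) in the parent. CXADR, a cell adhesion molecule and virus receptor, fell (-4.37 ± 0.50), and so did the tetraspanin CD9 (-2.82 ± 0.22) and FEZ1, an adaptor known from axon growth (-3.86 ± 0.36), for which a second probe set gave -0.04. PDGFA itself gave -0.14 ± 0.21 (adjusted p = 0.706), and whether its probe set detects the construct, the endogenous gene or both is not known. PDGFB lay below the intensity filter, at 103 ± 10.4 in the neo clones and 199 ± 122 in clone 8.1 (SD, n = 6 and n = 3). The receptor PDGFRB rose by 1.05 ± 0.22 (adjusted p = 0.00676; second probe set 1.25), while PDGFRA gave -0.17 ± 0.44 (adjusted p = 0.841). SREBF2, which encodes SREBP-2, fell by 0.69 ± 0.14 (adjusted p = 0.00570), and SREBF1 gave -0.46 ± 0.18 (adjusted p = 0.116). In the list of PDGF family and SREBP genes these were the only calls, 1 rise and 1 fall among 9 measured of 13 (median -0.17, adjusted p = 0.225).

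Cell cycle and inflammatory genes were higher in clone 8.1 than in the neo clones, as lists. In the DNA replication list 10 of 29 measured genes rose, 17 when adjusted over the list alone, among them CCNE1 (cyclin E) at 1.01 ± 0.18 and the polymerase subunit POLE2 at 1.74 ± 0.31. The median was 0.64 (adjusted p = 9.68e-07, but adjusted p = 0.363 with an estimated correlation). In the mitosis list 10 of 28 rose, 18 when adjusted over the list alone, with MKI67, the proliferation marker, at 1.12 ± 0.19 and TOP2A, a topoisomerase, at 1.62 ± 0.30. Here the median was 0.76 (adjusted p = 2.38e-07, but adjusted p = 0.363 with an estimated correlation). Clone 3.1 replicate 3 stood apart from the other neo arrays on both lists, at 0.86 and 0.81 relative to the mean of all 6, and without it the medians were 0.86 and 1.01. Of 15 inflammatory genes 7 rose, 10 when adjusted over the list alone, with RELB, an NF-kB subunit, at 1.32 ± 0.15, the NF-kB inhibitor NFKBIA at 1.47 ± 0.23 and the adhesion molecule ICAM1 at 1.54 ± 0.31. The inflammatory median was 1.01 (adjusted p = 1.75e-06, but adjusted p = 0.274 with an estimated correlation). That median rested on clone 8.1 no PDGF replicate 1, at 1.84 against 0.62 and 0.65 for the others, and was 0.55 without it (adjusted p = 3.26e-04). Within scan days 2 and 3, the medians were 1.00 and 0.36 for replication and 1.73 and 0.33 for mitosis. They were 0.74 and 1.07 for inflammatory genes and -0.45 and -0.54 for glycolysis. Against the parent, replication, mitosis and inflammatory genes were lower in clone 8.1, as given under that comparison.

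Glycolysis and hypoxia genes fell as a list, with 5 of 22 measured called by either count and none higher. Their median was -0.35 (adjusted p = 2.41e-04, but adjusted p = 0.363 with an estimated correlation). SLC2A3, a glucose transporter, fell (-0.94 ± 0.25), but was not called without clone 3.3 replicate 2 (-0.85), clone 8.1 no PDGF replicate 2 (-0.81) or clone 8.1 no PDGF replicate 3 (-0.68). The contractile list moved up, with ACTA2, smooth muscle actin, at 1.08 ± 0.18 and TAGLN at 1.81 ± 0.37 as the only 2 of 12 called, 6 when adjusted over the list alone. The contractile median was 0.41 (adjusted p = 0.0202, but adjusted p = 0.407 with an estimated correlation). That list was no longer called without clone 3.1 replicate 3 (median 0.37, adjusted p = 0.0744), clone 8.1 no PDGF replicate 1 (0.19, adjusted p = 0.184) or clone 8.1 no PDGF replicate 3 (0.35, adjusted p = 0.0667). In the matrix list 6 genes rose and 2 fell of 25, with THBS1, a thrombospondin, at 1.92 ± 0.26 and the basement membrane collagen COL4A2 at 1.71 ± 0.27. Its test gave adjusted p = 0.0858 (median 0.20). Of 16 ERK feedback genes 3 rose, including SPRED2 at 0.62 ± 0.13 and the ERK phosphatase DUSP6 at 1.38 ± 0.31 (median 0.49, adjusted p = 0.0621). The remaining lists were not called. Interferon genes had 2 rises, with IFIT3 at 0.89 ± 0.14, and 1 fall among 16 (median 0.21, adjusted p = 0.162). Immediate early genes had 1 rise and 1 fall among 19. Their median was 0.03 while their mean, -0.04, and the test pointed down (adjusted p = 0.745). The p53 targets had 1 rise and 1 fall among 10, with a median of 0.04, a mean of 0.03 and a test that pointed down (adjusted p = 0.921). Unfolded protein genes had 1 rise among 14 (median 0.11, adjusted p = 0.871), and none of 9 heat shock genes was called (median 0.26, adjusted p = 0.225).

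In all, limma called 995 of 7535 probe sets at an adjusted p under 0.05, 563 higher and 432 lower (349 and 717 with arrays scaled to equal medians, which moved the median of all probe sets by -0.12, and 448 and 510 with quantile normalization). Of the 995, 302 changed at least 2-fold. The arrays of the compared groups did not overlap for 1107 probe sets, where chance gives 2.38%. Without clone 8.1 no PDGF replicate 3, 626 were called, and PADI2 was not (log2 change 2.10, adjusted p = 0.0537; from 0.00347 to 0.135 over its settings). With scan day as a block and clone 3.1 alone as the control, 334 were called, from 8 arrays with 3 residual degrees of freedom. Of the 61 genes called among those the rule names here, 31 were then not called, all in the same direction and 29 with a wider error. They kept 64.9% to 140% of their change. The largest were at 2.54 ± 0.56 for CCL2, -3.46 ± 0.75 for CXADR, 1.89 ± 0.66 for LUM, 2.00 ± 0.63 for PADI2 and -2.59 ± 0.60 for PRSS3, and the others included PDGFRB (0.71 ± 0.25), CCNE1 (0.88 ± 0.22), SPRED2 (0.48 ± 0.14), ACTA2 (0.81 ± 0.24), TAGLN (1.18 ± 0.51), THBS1 (1.57 ± 0.38), SLC2A3 (-1.19 ± 0.29), NFKBIA (1.74 ± 0.36), ICAM1 (1.38 ± 0.31), IFIT3 (0.78 ± 0.22) and FAP (0.78 ± 0.30). The contractile list, at a median of 0.18, and the fibroblast or mural list, at 0.74, were no longer called with this block either. With 1 mean per cell line, so that the spread is that between 3 control lines, limma called 0. There 404 probe sets had an unadjusted p under 0.05 (5.36%), near the share of 0.05 that chance gives.

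Adding PDGF to clone 8.1 asks which transcripts respond to the factor in the cells that carry the dominant-negative. The sterol and fatty acid genes rose together. MVD went from 75 ± 26.4 to 2452 ± 213 (SD, n = 3 each), a log2 change of 4.59 ± 0.24 (adjusted p = 5.12e-08), and HMGCS1 from 279 ± 80.2 to 4634 ± 297, a change of 3.95 ± 0.20 (adjusted p = 5.12e-08). IDI1 rose by 1.94 ± 0.13, FASN by 2.36 ± 0.13, FADS2 by 2.86 ± 0.39, LPIN1 by 2.21 ± 0.20 and ELOVL5, a fatty acid elongase, by 1.08 ± 0.16. In the sterol list 14 of 16 measured genes rose by either count and none fell (median 1.81, adjusted p = 1.50e-21, and adjusted p = 0.0146 with an estimated correlation). In the fatty acid list 8 of 11 rose, 9 when adjusted over the list alone (median 1.08, adjusted p = 6.49e-10, and adjusted p = 0.0148 with an estimated correlation). All arrays with PDGF were scanned on day 5 and those of clone 8.1 without it on days 1 to 3, so no scan day gives a value of its own. Chip lot 3 held 2 arrays with PDGF and 1 without, and there the medians were 1.60 for sterol and 0.95 for fatty acid genes. With chip lot as a block, both lists pooled gave 1.62, against 1.65 without it.

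Replication and mitosis genes rose with PDGF. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, rose by 2.00 ± 0.18 (adjusted p = 7.46e-06), MKI67 by 1.83 ± 0.22, the mitotic kinase PLK1 by 1.09 ± 0.16, the ribonucleotide reductase subunit RRM2 by 2.24 ± 0.36 and CCNE2 (a cyclin E) by 2.11 ± 0.34. Of 29 replication genes 23 rose, 27 when adjusted over the list alone, and of 28 mitosis genes 24 rose, 27 when adjusted over the list alone. None fell. Their medians were 1.19 and 1.43 (adjusted p = 2.47e-16 and 1.78e-21, but adjusted p = 0.124 for both with an estimated correlation). Within chip lot 3 the medians were 1.45 and 1.91. Inflammatory genes fell, 6 of 15 and 12 when adjusted over the list alone, with ICAM1 at -2.67 ± 0.36, RELB at -1.16 ± 0.18 and the chemokine CXCL8 at -3.52 ± 0.55. Their median was -1.44 (adjusted p = 2.27e-07, but adjusted p = 0.124 with an estimated correlation), and within chip lot 3 it was -0.99. Without clone 8.1 no PDGF replicate 1, the array high on this list, it was -1.02 (adjusted p = 5.34e-05). Glycolysis and hypoxia genes fell, 7 of 22 by either count and none higher, with the hexokinase HK2 at -2.15 ± 0.23, the hypoxia-induced peptide ADM at -1.95 ± 0.22 and NDRG1 at -1.81 ± 0.30. Their median of -0.30 (adjusted p = 0.00164, but adjusted p = 0.476 with an estimated correlation) was -0.19 within chip lot 3, and -0.06 and no longer called without clone 8.1 no PDGF replicate 1 (adjusted p = 0.120).

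The other genes that rose most were ITGA2, a collagen-binding integrin, from 293 ± 235 to 3557 ± 543 (SD, n = 3 each; 3.70 ± 0.45, adjusted p = 1.21e-04), and ACTG2, a smooth muscle actin, from 368 ± 254 to 4157 ± 295 (3.62 ± 0.41, adjusted p = 7.21e-05). Next came the activin antagonist FST (2.83 ± 0.40), the small GTPase DIRAS3 (2.87 ± 0.24), the closely related trypsinogen genes PRSS3 (2.99 ± 0.38) and PRSS2 (2.50 ± 0.30), and CD9 (2.48 ± 0.25). The largest decreases were those of LUM (-4.38 ± 0.55, adjusted p = 1.63e-04), the matrix protease MMP3 (-3.93 ± 0.90, adjusted p = 0.0106), IGFBP4 (-3.68 ± 0.58), CCL2 (-3.53 ± 0.45), CXCL8, NINJ1 (-3.38 ± 0.47), PDZRN3, STC2, PPL and MXI1. MXI1, a repressor of the MYC network, was at -2.92 ± 0.26 and between -2.44 and -3.44 over its 3 probe sets. PDZRN3, STC2 and PPL lay between -3.11 ± 0.25 (PDZRN3) and -2.96 ± 0.21 (PPL). PDGFA gave -0.08 ± 0.24 (adjusted p = 0.871) and SREBF1 0.07 ± 0.21 (adjusted p = 0.871). PDGFRA rose by 1.96 ± 0.51 (adjusted p = 0.0203; other probe sets 1.37 and -0.05). PDGFRB fell (-0.96 ± 0.25, adjusted p = 0.0227; second probe set -1.03, not called at adjusted p = 0.0557) and SREBF2 rose by 0.64 ± 0.16 (adjusted p = 0.0186). These 3 calls were near the threshold. Without clone 8.1 no PDGF replicate 1 PDGFRA gave 1.28 (adjusted p = 0.0544) and PDGFRB -0.62 (adjusted p = 0.0600). PDGFRA also lost its call without clone 8.1 plus PDGF replicate 1 (1.98), replicate 2 (2.01) or replicate 3 (1.90), PDGFRB without replicate 1 (-0.99) or 2 (-0.86), and SREBF2 without replicate 2 (0.56) or 3 (0.65). With chip lot as a block PDGFRA gave 1.15 (adjusted p = 0.0575) and PDGFRB -0.84 (adjusted p = 0.0789). Over their settings adjusted p ran from 0.00626 to 0.0671 for PDGFRA, from 0.0147 to 0.0898 for PDGFRB and from 0.0103 to 0.0822 for SREBF2.

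**Figure D2:**
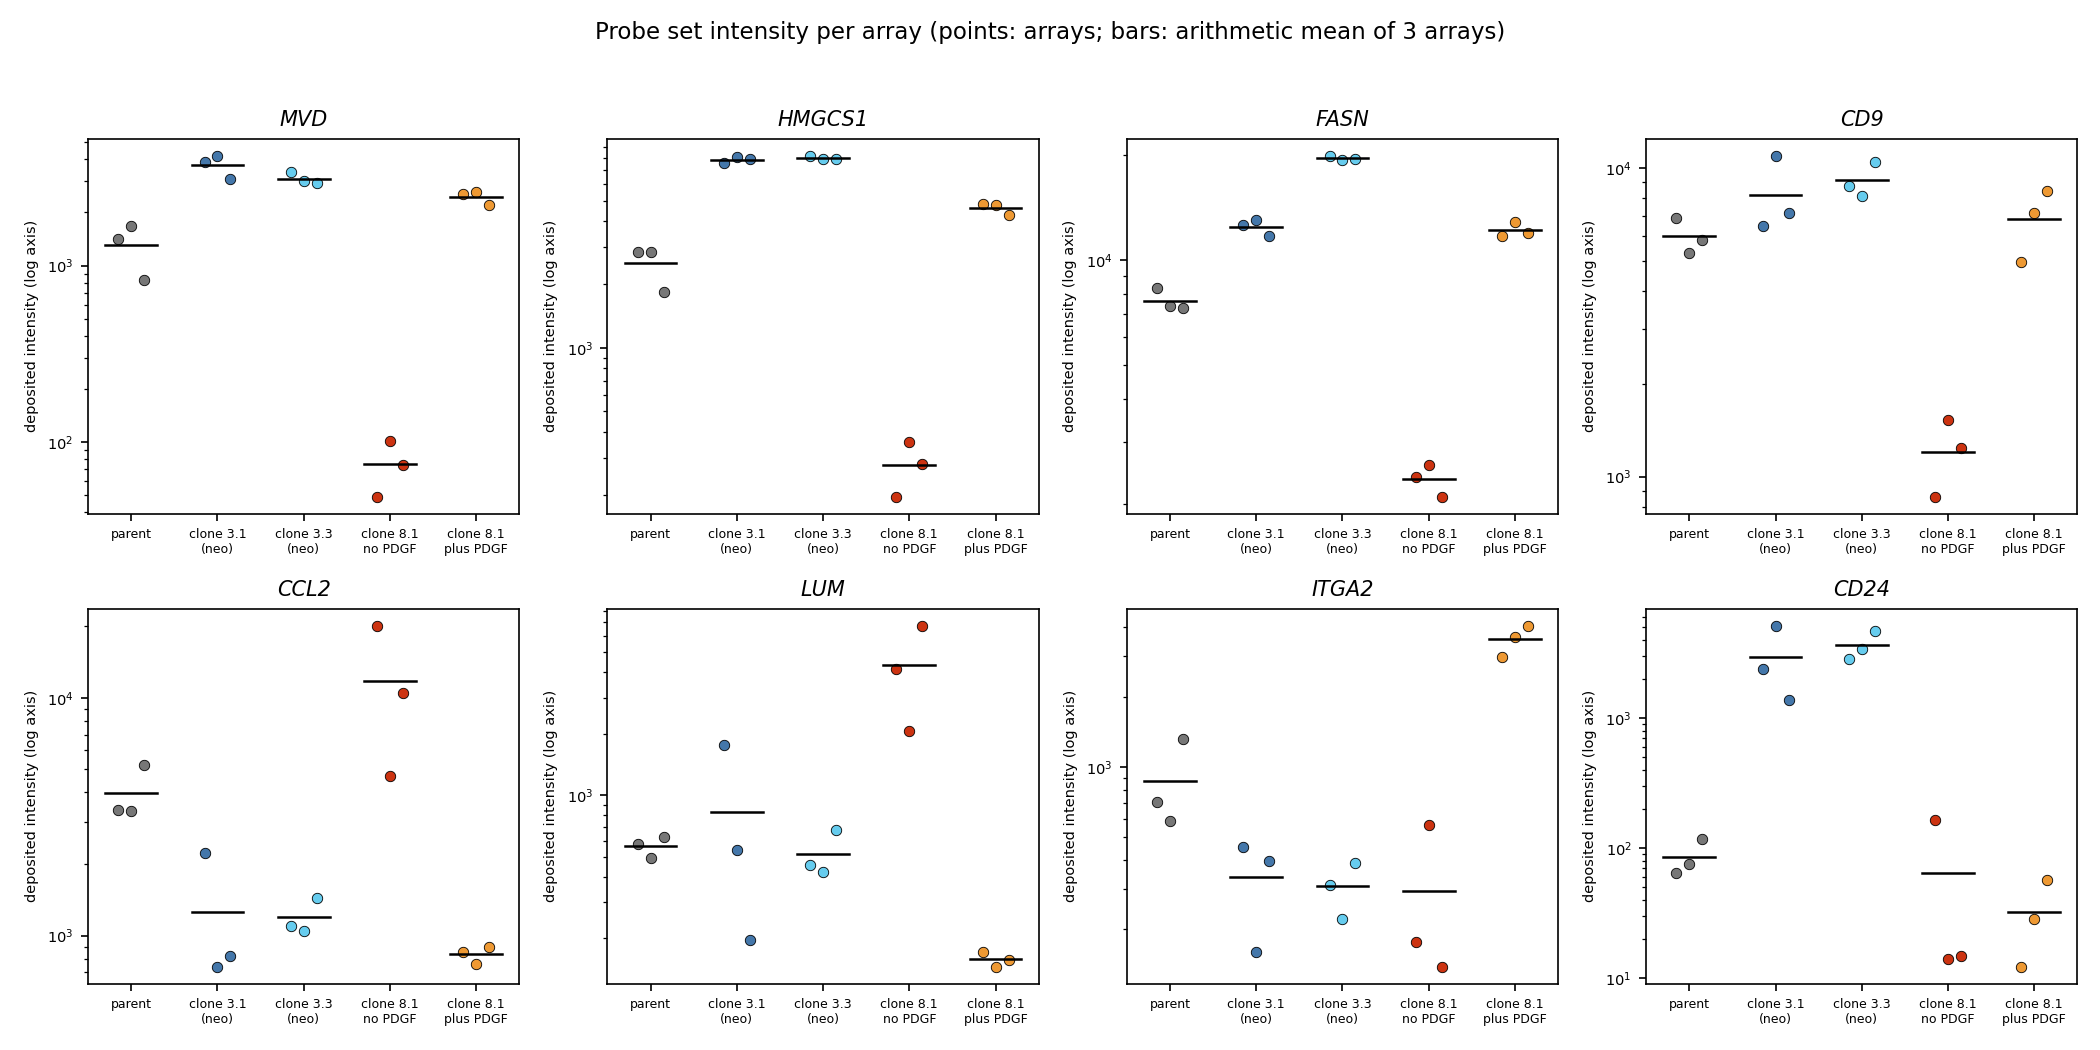
Deposited intensity (log scale) of 8 genes on each of the 15 arrays, with points for arrays and bars for group means. MVD and HMGCS1 were lowest on the 3 arrays of clone 8.1 without PDGF, at means of 75 and 279, and CD24 was high only in the neo clones.

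The other lists were not called with PDGF. In the PDGF family and SREBP list 2 genes rose and 2 fell of 9, PDGFRA, PDGFRB, SREBF2 and SCAP (median -0.23, adjusted p = 0.785). SCAP, the escort protein of SREBP, at -0.77 ± 0.19, was not called without clone 8.1 plus PDGF replicate 3 (-0.73, adjusted p = 0.0565; from 0.00397 to 0.0695 over its settings). Among immediate early genes 1 of 19 fell, the phosphatase DUSP1 at -1.53 ± 0.28 (median -0.09, adjusted p = 0.838). None of 16 ERK feedback genes was called (median 0.24, adjusted p = 0.175). The contractile list had 2 rises, ACTG2 and ACTA2, and 1 fall, the myosin light chain MYL9 at -1.35 ± 0.27. Its median was -0.09 while its mean, 0.15, and the test pointed up (adjusted p = 0.838). In the matrix list the proteoglycan VCAN rose by 1.89 ± 0.38 and 3 of 25 genes fell, LUM and MMP3 among them (median -0.03, adjusted p = 0.838). Unfolded protein genes had 1 fall, CEBPB at -1.20 ± 0.19, among 14 (median -0.04, adjusted p = 0.838), and p53 targets 1 among 10 (median -0.01, adjusted p = 0.838). Interferon genes had 1 rise, IFI44L at 1.01 ± 0.17, among 16 (median -0.25, adjusted p = 0.663), and heat shock genes 2 among 9 (median 0.24, adjusted p = 0.166). In all 984 of 7535 probe sets were called, 512 higher and 472 lower, 459 of them at least 2-fold, and 2265 did not overlap, where chance gives 10%. Without clone 8.1 plus PDGF replicate 2, 622 were called, and without replicate 3, 597.

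The set called in both comparisons with opposite signs shows which transcripts moved away from the neo clones in clone 8.1 and moved back with PDGF. No neo clone or parent array was labelled with PDGF. A reversal of the effect of the construct is therefore not separated from a response to PDGF that any of these lines might show. By the size of the smaller change it was led by the lipid genes MVD, HMGCS1, FADS2, MSMO1 (-3.16 ± 0.16, then 2.41 ± 0.18) and FASN (-2.72 ± 0.11, then 2.36 ± 0.13). CD9 (-2.82 ± 0.22, then 2.48 ± 0.25) and PRSS3 (-2.64 ± 0.33, then 2.99 ± 0.38) were also lower and then higher, and CCL2, LUM and IGFBP4 were higher and then lower. The set held 231 probe sets, 119 lower then higher and 112 higher then lower, and 90 more were called in both comparisons in the same direction. Independent lists of these sizes would share 64.6 with opposite signs and 65.3 with the same sign. The comparisons share the 3 arrays of clone 8.1 without PDGF, which ties their errors with opposite signs. Part of the excess may come from these arrays. When they were split, 1 or 2 for either comparison and the others for the other, in a test added later, 63 to 89 probe sets had opposite signs and 6 to 44 the same sign over the 6 ways. Independent lists of those sizes would share 7.04 to 19.99 with opposite signs and 7.01 to 20.02 with the same sign, so the same sign was in excess too in some ways (44 against 16.9). The covariance of the paired changes over these 6 ways ran from -0.0492 to -0.00229. In 100 simulations of unchanged groups at most 1 probe set was called in each comparison, so their count with opposite signs, at most 1, does not measure what the shared arrays add among real changes. The covariance of the paired changes was -0.082 over all probe sets, against a mean of -0.032 in the simulations, a difference of -0.050. Their correlation was -0.29, against a mean of -0.58 in the simulations.

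Clone 8.1 with PDGF against the neo clones shows what differed once PDGF was added. Of the 2045 probe sets called here, 1470 were not called without PDGF, those of ITGA2, NINJ1 and ACTG2 among them. The comparison thus holds both differences that stayed and differences called only with PDGF. Replication and mitosis genes stood above the neo clones on nearly the whole lists. CDC45, a helicase component, was higher by 3.80 ± 0.53, TOP2A by 3.33 ± 0.30, UBE2C by 2.63 ± 0.16, MKI67 by 2.95 ± 0.19 and CCNE2 by 3.30 ± 0.30 (adjusted p = 4.94e-06). Of 29 replication genes 27 rose and of 28 mitosis genes 27, by either count, with medians of 1.82 and 2.29 (adjusted p = 3.16e-20 and 1.49e-23, but adjusted p = 0.183 for both with an estimated correlation). Within scan day 5, which held 3 arrays with PDGF and 1 of clone 3.3, the medians were 1.98 and 2.04. Glycolysis and hypoxia genes were lower, 15 of 22 called, 16 when adjusted over the list alone, with ADM at -1.97 ± 0.19, HK2 at -1.81 ± 0.20 and PDK1, a brake on pyruvate oxidation, at -1.90 ± 0.27. Their median was -0.69 (-0.65 within scan day 5; adjusted p = 3.75e-08, but adjusted p = 0.222 with an estimated correlation). ERK feedback genes rose, 7 of 16 by either count, with SPRED2 at 0.77 ± 0.13, SPRY2 at 1.89 ± 0.34 and CCND1 (cyclin D) at 1.13 ± 0.27. The ERK median was 0.76 (adjusted p = 0.00586, but adjusted p = 0.222 with an estimated correlation). ACTG2 led the named genes at 4.72 ± 0.35, followed by SPC25, a kinetochore protein, at 3.46 ± 0.49 (0.32 by another probe set) and ITGA2 at 3.41 ± 0.39. CD24 at -5.67 ± 0.46, CXADR at -4.03 ± 0.50, NINJ1 at -3.33 ± 0.41, FEZ1 at -3.12 ± 0.36 and ZER1 at -2.93 ± 0.25 were lower. PDGFRA was higher by 1.79 ± 0.44 (adjusted p = 0.00767; other probe sets 1.47 and -0.07).

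The lipid genes had moved most of the way toward the neo clones. The sterol list had 4 genes lower, with HMGCS1 at -0.77 ± 0.17 and MSMO1 at -0.75 ± 0.16, and 1 higher of 16. The median was -0.37 (adjusted p = 0.0491, but adjusted p = 0.630 with an estimated correlation). That call ended without clone 3.1 replicate 1 (median -0.40), clone 3.1 replicate 2 (-0.39), clone 3.3 replicate 3 (-0.32), clone 8.1 no PDGF replicate 3 (-0.37) or clone 8.1 plus PDGF replicate 3 (-0.38). The fatty acid list had 2 of 11 lower, none when adjusted over the list alone (median -0.18, adjusted p = 0.200). Heat shock genes rose, 4 of 9 by either count, with the chaperones HSPD1 at 0.86 ± 0.15 and DNAJB1 at 0.90 ± 0.17. That list had a median of 0.57 (adjusted p = 0.0427, but adjusted p = 0.222 with an estimated correlation), and its call ended without clone 3.1 replicate 1 (0.62), clone 3.1 replicate 2 (0.49) or clone 8.1 no PDGF replicate 1 (0.57). The matrix list had 7 genes higher, COL4A2 at 2.64 ± 0.27 among them, and 3 lower of 25 (median 0.19, adjusted p = 0.311). The 7 lists left were not called either (adjusted p from 0.116 to 0.951). The unfolded protein list had a median of 0.04 but a mean of -0.04. In all 2045 probe sets were called, 1060 higher and 985 lower (869 and 1171 with equal medians, 973 and 1055 with quantile normalization), 674 of them at least 2-fold, and 2022 did not overlap, where chance gives 2.38%. Of the 995 called in clone 8.1 without PDGF, 549 (55.2%) were called here in the same direction and 420 were not called. Both comparisons use the same 6 neo arrays, which ties their errors in the same direction, and independent lists would share 136 in that direction. With the neo arrays split, 3 for each comparison, in a test added later, 225 to 408 were called in both in the same direction over the 20 ways (38.8% to 50.1%), where independent lists share 59.1 to 88.3. Of the 231 with opposite signs 183 were not called. With scan day as a block and clone 3.3 alone as the control 1058 were called. With 1 mean per cell line limma called 0, with 736 probe sets at an unadjusted p under 0.05 (9.77%).

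The comparison of clones 3.1 and 3.3 measures how far clones of the same kind differ. No gene was called: limma called 0 of 7535 probe sets, with 670 at an unadjusted p under 0.05 (8.89%). The smallest adjusted p was 0.0677, and 1279 probe sets did not overlap, where chance gives 10%. As a list, replication genes were higher in clone 3.1 (median 0.52, adjusted p = 1.46e-08) and so were immediate early genes (0.30, adjusted p = 0.00146). Matrix genes (-0.29, adjusted p = 0.00184), fatty acid genes (-0.34, adjusted p = 0.00913) and glycolysis genes (-0.18, adjusted p = 0.00913) were lower. With an estimated correlation none of these lists was called (adjusted p = 0.686 for glycolysis and 0.568 for the other 4). Without clone 3.1 replicate 3 the replication median was 0.18, the matrix median -0.15 and the glycolysis median -0.03, none of them called. Without clone 3.1 replicate 1 the fatty acid median was -0.21 and not called, the matrix median -0.58 and the glycolysis median -0.34. Without clone 3.3 replicate 2 the glycolysis list was not called (-0.11). The clones shared no scan day among arrays of known day, and that of clone 3.1 replicate 3 is not known. Within chip lot 3 (1 array against 2) the replication median was 0.40, the fatty acid median -0.52 and the glycolysis median 0.02. The other 10 lists were not called, with adjusted p from 0.141 to 0.885. Sterol genes had a median of -0.01.

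The neo clones against the parent compare control clones, which went through selection without the dominant-negative, with the line they came from. Differences in culture state are not separated from it. Secreted cytokines fell most. IL1B, the precursor of interleukin-1 beta, had an intensity of 32508 ± 15224 in the parent (SD, n = 3) and 1119 ± 651 in the neo clones (SD, n = 6), a log2 change of -4.83 ± 0.32 (adjusted p = 1.12e-06). CSF3, a granulocyte growth factor, IL6, IL11 and CXCL8 changed by -5.43 ± 0.45, -5.05 ± 0.58, -4.95 ± 0.58 and -4.57 ± 0.48. Of 15 inflammatory genes 14 fell by either count (median -2.84, adjusted p = 2.39e-12, but adjusted p = 0.0774 with an estimated correlation). Parent replicate 3 stood apart, at 1.72 above the neo mean against 3.61 and 3.52 for the others, and without it the median was -3.57. Mitosis and replication genes were lower in the neo clones, 26 of 28 and 22 of 29 called, 27 and 25 when adjusted over the lists alone, with UBE2C at -1.63 ± 0.16 and CCNE2 at -2.16 ± 0.30. Their medians were -1.65 and -1.15 (adjusted p = 1.62e-18 and 4.78e-14, but adjusted p = 0.139 for both with an estimated correlation). ERK feedback genes fell, 10 of 16, or 13 with 1 rise when adjusted over the list alone, with PLAUR at -1.92 ± 0.23 and DUSP6 at -2.13 ± 0.31. Their median was -0.93 (adjusted p = 3.98e-06, but adjusted p = 0.0774 with an estimated correlation). Sterol and fatty acid genes were higher, 8 of 16 and 6 of 11 (8 and 7 when adjusted over the lists alone, with 1 fatty acid gene lower), with HMGCS1 at 1.66 ± 0.17 and FASN at 1.03 ± 0.11. These lists had medians of 0.51 and 0.52 (adjusted p = 1.11e-05 and 0.00101, but adjusted p = 0.139 for both with an estimated correlation). Within scan day 3 (1 array of clone 3.1 against 2 of the parent) the medians were -3.05 for inflammatory, -1.67 for mitosis and -1.10 for replication. They were 0.48 for sterol and 0.43 for fatty acid genes.

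CD24 rose by 4.75 ± 0.46 in the neo clones, MYL1, a muscle myosin light chain, by 4.37 ± 0.56, the matrix protein MFAP4 by 3.63 ± 0.32, the receptor LTBR by 2.89 ± 0.13, and the lysosomal enzyme GALC by 2.87 ± 0.20. PDGFRA rose by 2.51 ± 0.44 (adjusted p = 0.00106), but its other probe sets gave 0.81 and 0.12 and were not called (adjusted p = 0.0709 and 0.659). Unfolded protein genes fell, 7 of 14 and 9 when adjusted over the list alone, with DDIT3, a stress-induced transcription factor, at -1.72 ± 0.24. That list had a median of -0.41 (adjusted p = 2.92e-04, but adjusted p = 0.161 with an estimated correlation). Matrix genes rose, 7 of 25 with 2 lower, by either count, with COL1A2, a chain of type I collagen, at 2.87 ± 0.21 and SPARC at 1.49 ± 0.13. The matrix median was 0.26 (adjusted p = 0.0394, but adjusted p = 0.596 with an estimated correlation), and that list was not called without clone 3.1 replicate 1 (0.16), clone 3.3 replicate 2 (0.26) or parent replicate 3 (0.23). The other 7 lists were not called, with adjusted p from 0.0962 to 0.706. The interferon list had a median of 0.05 but a mean of -0.05, and the heat shock list a median of -0.12 but a mean of 0.03. In all 1667 probe sets were called, 795 higher and 872 lower in the neo clones (970 and 727 with equal medians, 879 and 798 with quantile normalization), 538 of them at least 2-fold, and 1753 did not overlap, where chance gives 2.38%. Without parent replicate 1, 1084 were called, and without parent replicate 2, 1109.

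Clone 8.1 without PDGF was also compared with the parent, the other control of the series. The lipid genes were again lower, with MVD at -3.65 ± 0.24 (adjusted p = 4.75e-07) and HMGCS1 at -3.05 ± 0.20. In the sterol list 13 of 16 fell, 14 when adjusted over the list alone (median -1.45, adjusted p = 8.68e-19, and adjusted p = 0.0238 with an estimated correlation). Lower too in the fatty acid list were 5 of 11, 6 when adjusted over the list alone (median -0.53, adjusted p = 3.49e-07, and adjusted p = 0.0425 with an estimated correlation). Replication and mitosis genes were lower than in the parent, 5 of 29 and 9 of 28 called, 5 and 17 when adjusted over the lists alone, with RFC5, a replication factor subunit, at 988 ± 111 against 2008 ± 195 (SD, n = 3 each) and CKS1B at -1.10 ± 0.22. This is the opposite direction to the comparison with the neo clones. Their medians were -0.53 and -0.86 (adjusted p = 8.25e-06 and 4.59e-10, but adjusted p = 0.352 and 0.258 with an estimated correlation). Inflammatory genes were lower too, 9 of 15, or 9 with 1 rise when adjusted over the list alone, with IL1B at -4.19 ± 0.38 and IL6 at -3.64 ± 0.67. Their median was -1.98 (adjusted p = 3.87e-04, but adjusted p = 0.258 with an estimated correlation). Within scan days 1 and 3 the sterol medians were -1.58 and -1.54, and the fatty acid medians -0.57 and -0.42. On the same days the replication medians were -0.50 and -0.68, and the mitosis medians -0.92 and -1.07. The inflammatory median was -0.08 on day 1 and -2.85 on day 3. That difference did not hold on day 1, which held clone 8.1 no PDGF replicate 1 and parent replicate 3. The inflammatory median was -2.25 without the former array and -2.71 without the latter.

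TGFB3, a growth factor of the TGF-beta family, rose from 245 ± 46.3 in the parent to 5205 ± 279 in clone 8.1 (SD, n = 3 each), a log2 change of 4.26 ± 0.19 (adjusted p = 1.15e-08). GALC, MFAP4, SERPINA6 and the granin SCG2 rose by 3.92 ± 0.23, 3.72 ± 0.37, 3.64 ± 0.40 and 3.57 ± 0.51. FEZ1 (-4.72 ± 0.42), the elastase inhibitor PI3 (-4.60 ± 0.58), TFPI2 (-4.40 ± 0.51), CSF3 (-4.39 ± 0.52) and IL11 (-4.20 ± 0.67) fell most. PDGFRA and PDGFRB were higher, by 2.34 ± 0.51 and 1.51 ± 0.25 (adjusted p = 0.00736 and 0.00140). The other probe sets of PDGFRA gave 0.91 and 0.10 and were not called (adjusted p = 0.112 and 0.808), and the second of PDGFRB gave 1.82. Matrix genes rose, 10 of 25 by either count and none lower, with COL1A2 at 2.60 ± 0.24 and COL5A2 at 2.24 ± 0.30 (median 0.54, adjusted p = 5.39e-06, but adjusted p = 0.258 with an estimated correlation). Contractile genes rose, 2 of 12 and 3 when adjusted over the list alone, with ACTA2 at 1.96 ± 0.20 (median 0.46, adjusted p = 3.87e-04, but adjusted p = 0.258 with an estimated correlation). ERK feedback genes fell, 6 of 16 with 1 higher, 7 and 1 when adjusted over the list alone (median -0.72, adjusted p = 3.87e-04, but adjusted p = 0.150 with an estimated correlation). Unfolded protein genes fell, 4 of 14 and 5 when adjusted over the list alone, with DDIT3 at -2.25 ± 0.28 (median -0.24, adjusted p = 8.18e-04, but adjusted p = 0.258 with an estimated correlation). That median was -0.36 without clone 8.1 no PDGF replicate 2, -0.15 without replicate 3, and -0.15, -0.15 and -0.46 without parent replicates 1, 2 and 3.

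Immediate early and glycolysis genes gave weak calls against the parent that single arrays decided. The immediate early list had 2 of 19 lower, ATF3 at -1.62 ± 0.29 among them (median -0.19, adjusted p = 0.0354, but adjusted p = 0.352 with an estimated correlation). It was not called without clone 8.1 no PDGF replicate 2 (-0.06) or 3 (-0.18) or parent replicate 1 (-0.20) or 2 (-0.19). Without clone 8.1 no PDGF replicate 1 or parent replicate 3 it was -0.52 and -0.32. The glycolysis list had 1 of 22 lower (median -0.14, adjusted p = 0.0375, but adjusted p = 0.572 with an estimated correlation). This list was not called without clone 8.1 no PDGF replicate 2 (-0.15) or 3 (-0.12) or parent replicate 2 (-0.13) or 3 (-0.16). Its median was -0.21 without clone 8.1 no PDGF replicate 1, and 0.04 within scan day 1. The PDGF family and SREBP list had a median of -0.06 but a mean of 0.33 (adjusted p = 0.556), and the p53, interferon and heat shock lists were not called (adjusted p = 0.749, 0.556 and 0.556). In all 951 probe sets were called, 532 higher and 419 lower (436 and 475 with equal medians), 454 of them at least 2-fold, and 2159 did not overlap, where chance gives 10%. Without parent replicate 1, 538 were called, and without parent replicate 2, 549.

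**Figure D3:**
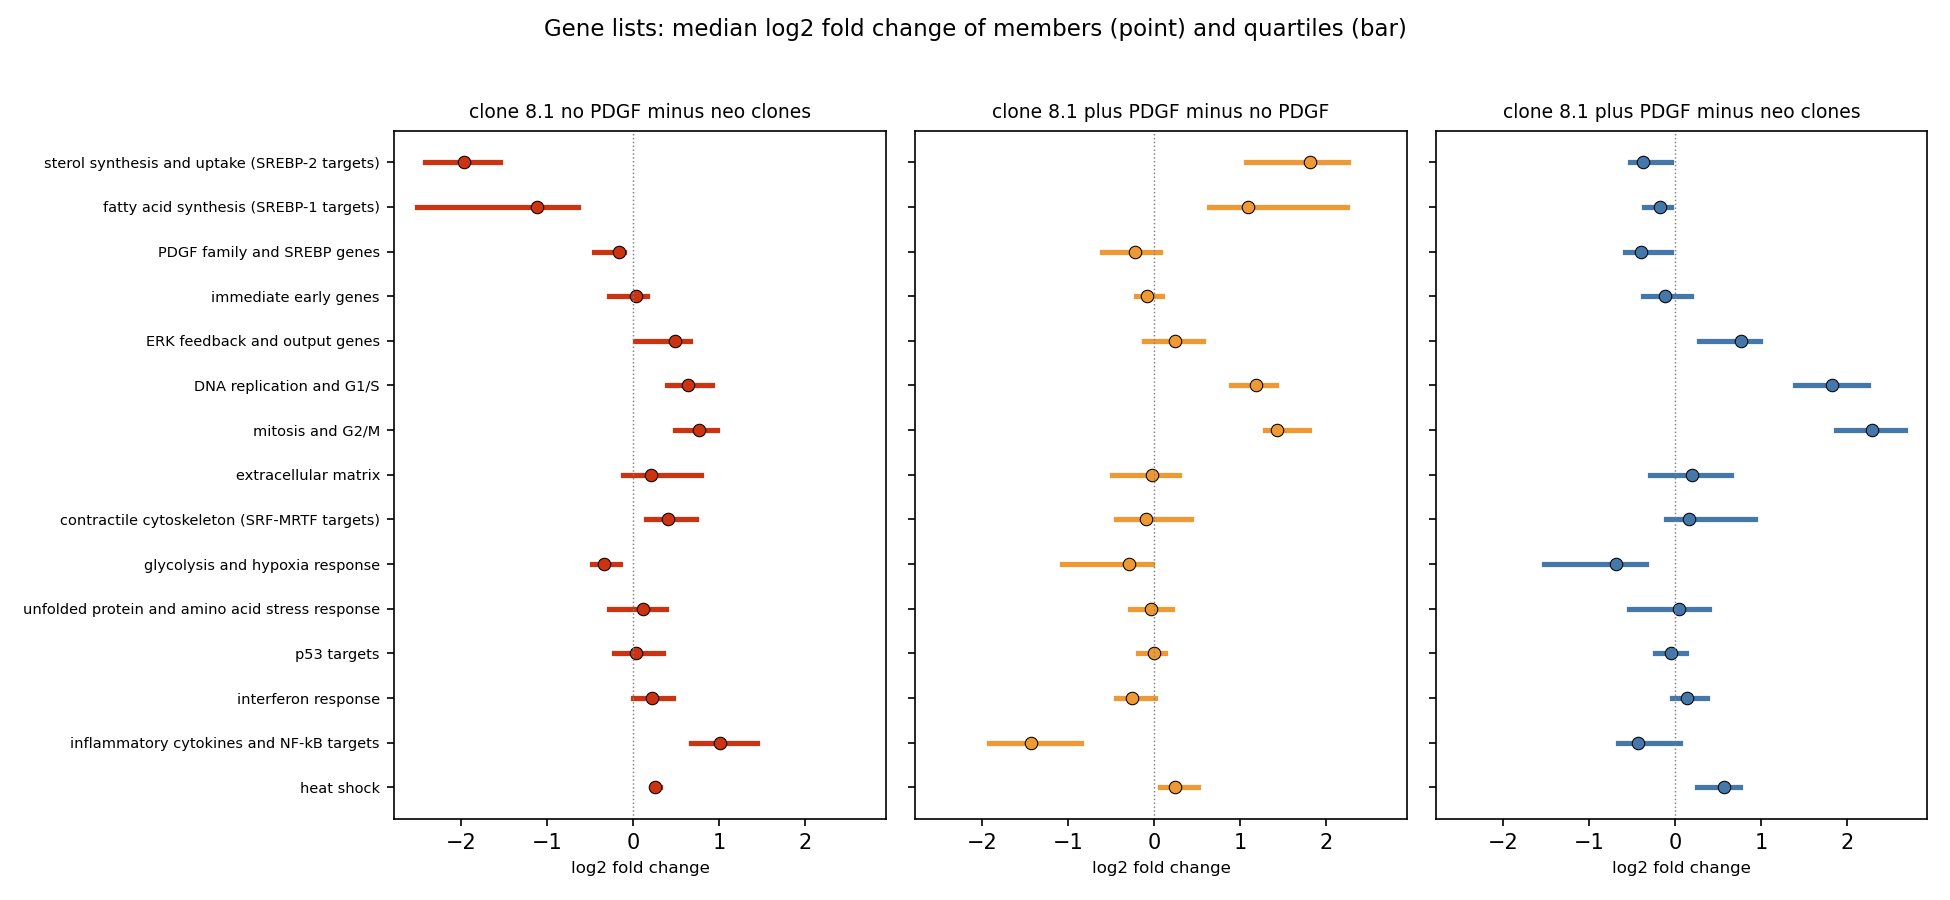
Median log2 change of each of the 15 gene lists, with lines for the quartiles of the members. The panels show clone 8.1 without PDGF against the neo clones, PDGF added to clone 8.1, and clone 8.1 with PDGF against the neo clones. The sterol list lay at -1.97, 1.81 and -0.37 in these panels.

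Markers of other cell types were compared because a clone can differ in its differentiation. Fibroblast and mural markers were higher in clone 8.1 without PDGF than in the neo clones, with LUM, PDGFRB and the protease FAP (1.04 ± 0.22) called, 3 of 4 measured by either count. The list (median 1.05, adjusted p = 0.0167, but adjusted p = 0.291 with an estimated correlation) was not called without clone 8.1 no PDGF replicate 1 (0.91). With PDGF 2 of them fell, 3 when adjusted over the list alone. Their median was -0.82 (adjusted p = 0.0389, but adjusted p = 0.614 with an estimated correlation), a call that ended without clone 3.1 replicate 2 (-0.82), clone 8.1 no PDGF replicate 1 (-0.68), clone 8.1 plus PDGF replicate 1 (-0.83) or parent replicate 3 (-0.82). Against the parent all 4 were higher in clone 8.1 (median 2.12, adjusted p = 7.06e-05, but adjusted p = 0.102 with an estimated correlation). Of 6 astroglial markers 2 fell in clone 8.1 against the neo clones, with FABP7, a fatty acid binding protein of radial glia, at -2.48 ± 0.24 (median -0.08, adjusted p = 0.148). With PDGF GJA1, a gap junction protein, fell (-1.03 ± 0.19) and CLU rose (0.81 ± 0.18; median -0.38, adjusted p = 0.717). In the neo clones 3 astroglial markers were higher than in the parent, 4 when adjusted over the list alone (median 0.61, adjusted p = 0.00689, but adjusted p = 0.0773 with an estimated correlation). Between the neo clones the list was lower in clone 3.1 (median -0.47, adjusted p = 0.00282, but adjusted p = 0.0524 with an estimated correlation). As a list, neuronal markers (5 measured) were not called in clone 8.1 against the neo clones or with PDGF (adjusted p = 0.693 and 0.940). TUBB3, a neuronal tubulin, fell in clone 8.1 against the neo clones (-0.49 ± 0.14) and rose with PDGF by 0.96 ± 0.16. Another marker, 1 of the 5, fell with PDGF. With PDGF this list had a median of -0.37 but a mean of 0.12. Oligodendroglial markers (4 measured) were not called as a list (adjusted p = 0.959 and 0.717), though CNP rose in clone 8.1 against the neo clones (0.48 ± 0.14). With PDGF CSPG4, a proteoglycan of progenitors, rose by 1.77 ± 0.36, and the median was -0.04 but the mean 0.35. Immune markers (4 measured) were not called as a list (adjusted p = 0.368 and 0.580). Of these 1 was higher in clone 8.1 than in the neo clones, CSF1R at 0.55 ± 0.14, and 1 fell with PDGF. Only 1 of 8 epithelial markers was measured, too few for a test.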

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

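The tests on the scan day, chip lot and line explanations below, on the neo clones' levels, on the scan delay and on the label of 1 parent array were chosen after the result was seen, and so were the splits of the samples except those for PDGF added to clone 8.1, for clone 3.1 against 3.3 and for clone 8.1 without PDGF against the parent. The test of a mixture was chosen before.

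The control probe sets were left out of all comparisons, and 2 of the control transcripts differed on every array between groups when limma was fitted to them. The transcript HUMISGF3A/M97935 was higher in clone 8.1 than in the neo clones, by 0.91 ± 0.15 without PDGF (SE, n = 3 and n = 6 arrays, adjusted p = 7.48e-06) and by 0.74 ± 0.15 with PDGF (adjusted p = 0.000166). The ribosomal control HUMRGE/M10098 was higher with PDGF than without by 0.65 ± 0.20 (n = 3 each, adjusted p = 0.0172).

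The sterol and fatty acid genes fell in clone 8.1 by a pooled median of 1.80 on the log2 scale and rose with PDGF by 1.65. Against scan day as the whole cause of the fall, the median within each of the 3 usable scan days was at most -1.38, while the arrays of a group differed by at most 0.33. Against scan day as the whole cause of the rise, clone 3.3, scanned on later days, exceeded clone 3.1 by an upper quartile of 0.26 over the genes (0.31 without the array of unknown day), below the lower quartile of 0.71 of the rise, and chip lot as a block kept 98.0% of the fall and the rise, whichever was lower. A difference between lines unrelated to the construct cannot be told apart from its effect for the fall, since only 1 clone carries it; control lines differed by at most 0.57, against -1.80 for clone 8.1. The contrast of clones 3.3 and 3.1 is a limited test of day 5. Only replicate 3 of clone 3.3 was scanned on day 5, the others on day 4, and a difference between these clones is not separated from scan day. A biological effect of PDGF, which the design names, stays open for the rise, and so does a part from scan day, since the arrays with PDGF shared day 5.

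Replication and mitosis genes with PDGF exceeded the neo clones by a pooled median of 2.04. Low levels in the neo clones alone would leave no excess over the parent, but there the median was 0.63, with a lower quartile of 0.33. With chip lot as a block the rise with PDGF was 103% of its value without. Against scan day as the whole cause, clone 3.3 exceeded the clone 3.1 arrays of known day by an upper quartile of 0.34, below the lower quartile of 1.14 of the rise, and within day 5 clone 8.1 with PDGF exceeded clone 3.3 by 2.00, with a lower quartile of 1.55. The contrast of clones 3.3 and 3.1 does not separate scan day from a difference between these clones, and clone 3.3 had only replicate 3 on day 5. What stays open is a biological effect of PDGF on proliferation, a difference in density or growth phase between cultures, which the labels do not give, and a part from scan day, which parts the groups with and without PDGF.

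Cytokine genes differed between arrays of 1 group: as the median over genes of each gene's difference, clone 8.1 no PDGF replicate 1 lay 0.84 above the mean of the other 2 arrays, which were 0.20 apart, and parent replicate 3 lay at -0.81 from its others, which were 0.06 apart. For a mixture of the RNA of these 2 arrays, the share of the way toward the other group was taken on the log2 scale. In the parent array it was 21.2% over 564 probe sets outside the list against 55.1% over the 10 genes of the list. In the other array it was 21.3% against 30.8%. The 8 other pairs of arrays gave -4.33% to 27.0% in the parent and 3.41% to 31.1% in clone 8.1. A mixture is linear in intensity, so its log2 share changes with the size of a gene's difference. Unequal shares therefore do not decide whether these 2 arrays were mixed. Both arrays had a delayed scan, but an error that moves them alike is excluded by the opposite signs of 0.84 and -0.81. Against a label from another group, parent replicate 3 lay at a median of at most 24.96% of the way to clone 3.3 or clone 8.1 with PDGF. Arrays of these 2 groups had lower quartiles of at least 72.3% when held out. For clone 3.1 and clone 8.1 without PDGF this measure could not decide. Its upper quartiles of 51.7% and 51.2% passed the lowest held-out lower quartiles of 31.7% and 44.2%. For them the sterol and fatty acid median was taken instead. At -0.52 on parent replicate 3, it lay 0.43 or more from every array of both, where groups ranged over at most 0.33. A label from clone 3.1 or clone 8.1 without PDGF is thus argued against by these 2 lists only. A fixed bound tried first, passed by upper quartiles of up to 53.2%, had left the label open. A mixture stays open, and so does a delay that acts differently in each line, or a difference between cultures or in RNA handling. A sample from outside the series also stays open, since the run information of parent replicate 3 words its sample differently.

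Other splits of the same arrays were fitted in the same way with limma. Chance in the grouping of single arrays can be excluded for clone 8.1 without PDGF against the neo clones (995 called, highest other split 194, 1 of 84 as large), for clone 8.1 with PDGF against them (2045, highest other 674, 1 of 84) and for the neo clones against the parent (1667, highest other 573, 1 of 84). These splits treat the arrays as exchangeable, the highest others exchange whole clones, and with 1 mean per cell line limma called 0 in clone 8.1 without and with PDGF (smallest adjusted p = 0.348 and 0.122), so a chance difference between lines is not excluded. For the opposed set 3 of 100 splits were as large as the 231 observed, under the share of 0.05, but the highest, 742, had the 3 arrays with PDGF as the group without it and points to a structure of the samples. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. There the real values and the highest others were 984 and 1 for PDGF added to clone 8.1 (1 of 10 as large), 951 and 1 for clone 8.1 without PDGF against the parent (1 of 10), and 0 and 0 for clone 3.1 against 3.3 (10 of 10, with 670 probe sets at an unadjusted p under 0.05).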

How the results depend on the processing

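The scan-day blocks with 1 neo clone as the control, scan day as a random block and the fits without the delayed-scan arrays were chosen after seeing the data, all other alternatives before. Over 38 settings no list or gene called in the main fit changed direction. Over the 7 counts 171 alternative values stayed within 1.5 times the main count and 40 did not. For the lists 3211 alternative values kept their side of the threshold, 125 lost the call and 37 gained it. A further 1 was not called in the main fit and was called in the other direction. Uncalled values that changed sign and stayed uncalled count as kept. For the named genes 14878 kept it, 927 lost it and 235 gained it. The sterol and fatty acid lists kept their call and direction in clone 8.1 and with PDGF under every alternative run.

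A stricter threshold lowered the counts by its construction. At an adjusted p under 0.01 limma called 398 in clone 8.1 against the neo clones, 439 with PDGF added, 102 opposed, 1158 in clone 8.1 with PDGF, 917 in the neo clones against the parent and 454 in clone 8.1 against the parent. With a 2-fold change as well as an adjusted p under 0.05 these were 302, 459, 102, 674, 538 and 454. With only the groups compared 632 were called in clone 8.1 against the neo clones and 534 against the parent, with fewer arrays in the model. Of probe sets called, clone 8.1 no PDGF against the neo clones gave 584 with clone 3.1 alone as the control and 872 with clone 3.3 alone. With scan day as a block, 334 were called against clone 3.1 and 1058 in clone 8.1 with PDGF against clone 3.3; the cause was not tested for these values. With 1 mean per cell line limma called 0 in clone 8.1 without and with PDGF, with 404 and 736 probe sets at an unadjusted p under 0.05 (5.36% and 9.77%). For clone 3.1 against 3.3, where 0 were called (670 at an unadjusted p under 0.05), the 25th percentile offset gave 3, no filter 1, the 60% filter 2, quantile normalization 1, equal medians 1, chip lot as a block 7 and leaving out the delayed-scan arrays 2; the cause was not tested.

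Scaling to equal medians moved the median change of all probe sets in clone 8.1 against the neo clones by -0.12, from 0.05 to -0.08, and the calls from 563 higher and 432 lower (56.6% higher) to 349 and 717 (32.7% higher), so the balance of directions depends on the scaling. It also turned in clone 8.1 with PDGF (from 51.8% higher to 42.6%), in the neo clones against the parent (from 47.7% to 57.2%) and in clone 8.1 against the parent (from 55.9% to 47.9%).

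With an estimated correlation the replication, mitosis, inflammatory and glycolysis lists lost their calls, both in clone 8.1 (medians 0.64, 0.76, 1.01 and -0.35, adjusted p from 0.274 to 0.363) and with PDGF added (1.19, 1.43, -1.44 and -0.30, adjusted p from 0.124 to 0.476), since members of a list vary together. With the parent among the controls the first 3 were 0.29, 0.18 and 0.14 in clone 8.1 and lost their calls, and so they did with 1 mean per cell line; the parent's levels lie above those of clone 8.1. Without the delayed-scan arrays the glycolysis list with PDGF was -0.064 and not called (adjusted p = 0.139, and from 7.99e-05 to 0.476 over its alternatives); the cause was not tested.

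Leaving out 1 array at a time gave 626 to 1195 probe sets called in clone 8.1 against the neo clones, 597 to 1207 with PDGF added, 157 to 256 opposed, 1392 to 2256 in clone 8.1 with PDGF, 0 to 4 for clone 3.1 against 3.3, 1084 to 1920 in the neo clones against the parent and 538 to 1151 in clone 8.1 against the parent. The lowest were those without clone 8.1 no PDGF replicate 3 (626), clone 8.1 plus PDGF replicate 3 (597) and replicate 2 (157 and 1392), and parent replicate 1 (1084 and 538), and the highest of 4 without clone 3.1 replicate 1. List medians ranged in clone 8.1 and with PDGF from -2.06 to -1.91 and 1.76 to 1.92 (sterol), -1.21 to -1.12 and 0.93 to 1.18 (fatty acid), 0.54 to 0.86 and 1.06 to 1.29 (replication), 0.59 to 1.01 and 1.25 to 1.61 (mitosis), 0.55 to 1.25 and -1.63 to -1.02 (inflammatory), and -0.51 to -0.25 and -0.38 to -0.064 (glycolysis).

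With chip number as a replicate block 580 were called in clone 8.1 against the neo clones, 578 against the parent and 1 for clone 3.1 against 3.3. Of probe sets called, PDGF added to clone 8.1 gave 714 with this block. Whether the numbers pair the arrays is not settled. Residuals of arrays with the same number correlated with a median r of 0.05 over 26 pairs (-0.14 to 0.25). The 52 other pairs had a median r of -0.04 (-0.21 to 0.25). Of the 14 numbered arrays, 7 correlated best with their own number. This block also left out the array without a number. MMP3 with PDGF was -3.19 and not called with the block (adjusted p = 0.0679, and from 0.00209 to 0.0679 over its alternatives), and SREBF2 was 0.57 and not called (adjusted p = 0.0729, and from 0.0103 to 0.0822).

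Signal over background limits the dim genes: 40% of probe sets were left out, PDGFB among them, and the offset of 29.9 shrinks changes of genes that were dim in clone 8.1, such as MVD, CD24 and FEZ1. In simulated data 24% of 1.5-fold changes and 84% of 2-fold changes were called in clone 8.1. That simulation changed 200 of 7535 probe sets and called 160, against 995 called in the data. The adjusted p depends on how many probe sets change, so these shares do not carry over to the data. Changes under 2-fold may still have gone uncalled.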

Other observations

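Of the 231 probe sets with opposite signs in the main comparisons, 22 were still called with PDGF on the side where they lay without it, 26 were called on the other side of the neo clones, and 183 were not called. A further 1470 probe sets were called in clone 8.1 with PDGF against the neo clones and not without PDGF. ACTG2 was one of these, at 4.72 ± 0.35 with PDGF (SE, n = 3 and n = 6 arrays) against 1.10 ± 0.35 without (limma adjusted p = 0.0540, and from 0.00482 to 0.429 over its alternatives).

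The ratio of the 3' to the 5' probe sets of the control transcripts, a measure of RNA integrity, lay between 0.837 and 1.01 for GAPDH and between 0.860 and 1.09 for ACTB over the 15 arrays.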
